A study of Mus musculus with 2 samples.

How the data were processed

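Total RNA of Mac-1-positive, c-Kit-positive, YFP-positive leukaemia cells was extracted, amplified and labelled with Cy3 by a low-input one-colour kit, per the labels' protocols. Each of the 2 arrays carried 45018 spots, of which 43379 were non-control spots of 41174 probes. Per the labels, 1 array held Jam3-null cells and 1 held WT cells, each from 3 mice. Whether the RNA of the mice was pooled in equal parts is not given in the sources used here.

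The spot intensities were made with Agilent Feature Extraction 10.7.3.1, per the file headers, and the submitters' processing notes name version 10.7. The processed intensity was background-subtracted, with spatial and multiplicative detrending within each array, and dim spots hold a surrogate value, per the file headers. These intensities were deposited on a linear scale and were not normalized between arrays. The deposited mean signal and local background intensities were used for an alternative background correction, and the deposited error of the processed intensity gave a measurement error per spot. The value table of the authors holds log2 values, which matched the log2 processed signals of the same probes (Pearson r over probes 0.999 on each array). Its median was 5.66 in both columns, whose sorted values differed by at most 0.00038, as after quantile normalization; the method is not given in the sources used here, and the table served as an alternative only.

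Both arrays were on 1 slide and in 1 scan, per the file headers, so slide and scan do not separate the genotypes. Spots flagged as non-uniform or population outliers were left out (151 non-control spots on the Jam3-null array and 163 on the WT array), and 0 non-control spots were saturated. The log2 processed signal minus the array's 75th percentile over non-control spots (667.8 and 713.9) was averaged over the spots of a probe. A gene took the values of its probe with the highest mean signal. Of genes compared, 5176 had several probes well above background on both arrays, and in 1301 of them these differed in sign; among the 761 of them at least 2-fold apart, 49 did. Probe accessions were matched without versions to a RefSeq gene table of the assembly GRCm38.p6, used for names only: 27668 probes were named by accession and 471 by a unique older symbol, and 13035 kept the name in the file. Coordinates are those of the array files, on mm9.

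A gene entered the comparison when its probe was well above background on both arrays (14361 of 27337 genes). For a gene well above background on 1 array only, the bright value was set against the higher of the lowest signal well above background on the dim array and the probe's own signal there, which gives a bound and no fold; 1724 genes had one in the measured direction. No fold is given where both arrays were below background (10018 genes).

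No test across samples was possible with 1 array per group. For each of 28 gene lists the median log2 difference was set against 10000 random lists of the same size drawn from 20 bins of mean signal, and a list stood apart outside their central 95%. Measurement error was taken from the error model (median SD of a log2 difference 0.20) and from 127 probes printed in repeat spots (median SD 0.09). Brightness over background sets the precision: repeat spots had an SD of the log2 difference of 0.24 in the dimmest of 4 equal groups of such probes and 0.07 in the brightest. Genes were named by a rule fixed beforehand: 20 focus genes; the 12 largest and 12 smallest log2 differences among genes measured on both arrays with a mean signal above the median, all measured probes changing the same way; the 4 largest bounds in each direction; and the 3 members of each list with the largest absolute difference. Unnamed and predicted genes were counted but not named, and 1 focus gene is not reported here.

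The gene-level and list steps were run on simulated probe values made from the real mean signals and error-model SDs. The background correction, scaling and spot filter were not part of this run. Of 200 changed genes among 14354, all 100 shifted by 1.5 in log2 and all 100 shifted by 3 passed 2-fold in the right direction, and 5 of 14154 unchanged genes passed it. Of 200 random lists of 22 genes 13 stood apart, and of 200 lists shifted by 1 in log2 on permuted real differences 200 did. Shifts this large against a median error-model SD of 0.20 should pass, so these numbers check the code and not the sensitivity on real samples.

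The alternatives were normexp background correction (offset 50), quantile normalization, cyclic loess, median scaling, the authors' value table, no filter and a stricter filter on dim probes, genes at their bound, the mean of a gene's probes, fold thresholds of 1.5 and 3, and, chosen after the data were examined, scaling on 8 E1A spike-in probes. The spike-in probes had a median log2 difference of 0.09 (from -0.02 to 0.12) after the main scaling. R 4.3.3 with limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.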

Results

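Gene expression was measured in leukemia-initiating cells, the fraction of a leukaemia defined by its capacity to start the disease again, from mouse acute myeloid leukaemias driven by the MLL-AF9 fusion. The cells were sorted from bone marrow as YFP-positive, Mac-1-positive and c-Kit-positive, and were either Jam3-null or wild type (WT). Jam3 encodes junctional adhesion molecule 3, a cell surface protein of the immunoglobulin superfamily. The data were 2 one-colour arrays, 1 per genotype, and the label of each array names 3 mice. On the Jam3-null array 55.0% of 43379 non-control spots were well above background, and on the WT array 61.8% were. The median processed signal was 49.3 and 51.6, respectively. With 1 array per genotype no difference below has a replicate check, no p-value is given across genes, and the number of arrays limits the precision of every value. Differences are log2 Jam3-null minus WT after scaling each array to its 75th percentile, so a positive value means a higher signal on the Jam3-null array.

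Jam3, the targeted gene, was read by 2 probes, and neither was well above background on either array. The probe at chromosome 9, 26905298 to 26905357 (mm9), had processed signals of 28.1 on the Jam3-null array and 5.09 on the WT array, and the probe at 26903515 to 26903574 had 5.40 and 3.23. No fold is given for Jam3, and the genotypes below are those of the labels, which this gene did not check. Whether either probe lies in the deleted part of Jam3 is not given in the sources used here.

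The comparison of the 2 arrays asked which transcripts differ in leukemia-initiating cells that lack Jam3. The Jam3-null array had higher signals for genes of maturing neutrophils, whereas cyclin and progenitor genes went both ways. All 22 measured neutrophil maturation genes were at least 2-fold higher, among them Fcnb, a secreted ficolin of neutrophil granules, at 99.1-fold and the integrin Itgb2l at 49.8-fold. Ccnd1, which encodes the G1 cyclin D1, was 62.5-fold lower (33.0-fold after normexp background correction), and Flt3 and Cd34, surface proteins of progenitor cells, were 11.4-fold and 10.6-fold lower. In the other direction, the stem and progenitor gene Ly6a was 2.41-fold higher. Cdkn1c, an inhibitor of cyclin-dependent kinases, was 40.6-fold higher, while Kit, used in the sort, differed by 0.09 in log2.

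Of 14361 genes well above background on both arrays, 1473 were at least 2-fold higher and 1234 at least 2-fold lower on the Jam3-null array. Which direction held more genes depended on the scaling: 1317 were higher and 1498 lower with spike-in scaling, chosen after the data were examined, and 1761 and 985 with cyclic loess. The spread of repeat spots within an array alone would give 0.0486 genes past 2-fold in each direction, and the scanner software's error model 2.18. Both cover measurement error only and leave out the spread between leukaemias and between animals. Repeat spots of an array also share its amplification, labelling and hybridization, so their spread leaves out the error of these steps. The error-model SD of the log2 difference was between 0.20 and 0.34 for the named genes measured on both arrays. A further 466 genes were well above background on the Jam3-null array alone and 2439 on the WT array alone. The lowest normalized log2 signal well above background was -4.69 on the Jam3-null array and -5.53 on the WT array, so dim genes pass more easily on the WT array, and these 2 counts do not give a balance of directions. All 466 had a bound in the measured direction but only 1258 of the 2439 did, and bounds of at least 2-fold were found for 452 genes higher and 384 lower on the Jam3-null array. The bounds are set against these floors, so a gene just above background gets a larger bound on the Jam3-null side. These counts therefore give no balance of directions either, and list medians with genes at their bound can lean upward. Folds of dim genes were smaller after normexp correction, whose offset of 50 is added to every signal and pulls them towards 0 by construction. The part of the offset was not separated from that of the background correction. Where normexp correction made a fold or bound given below more than 1.5 times smaller, the log2 value after it follows in brackets. Figure captions and values already given after that correction have no brackets.

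**Figure D1:**
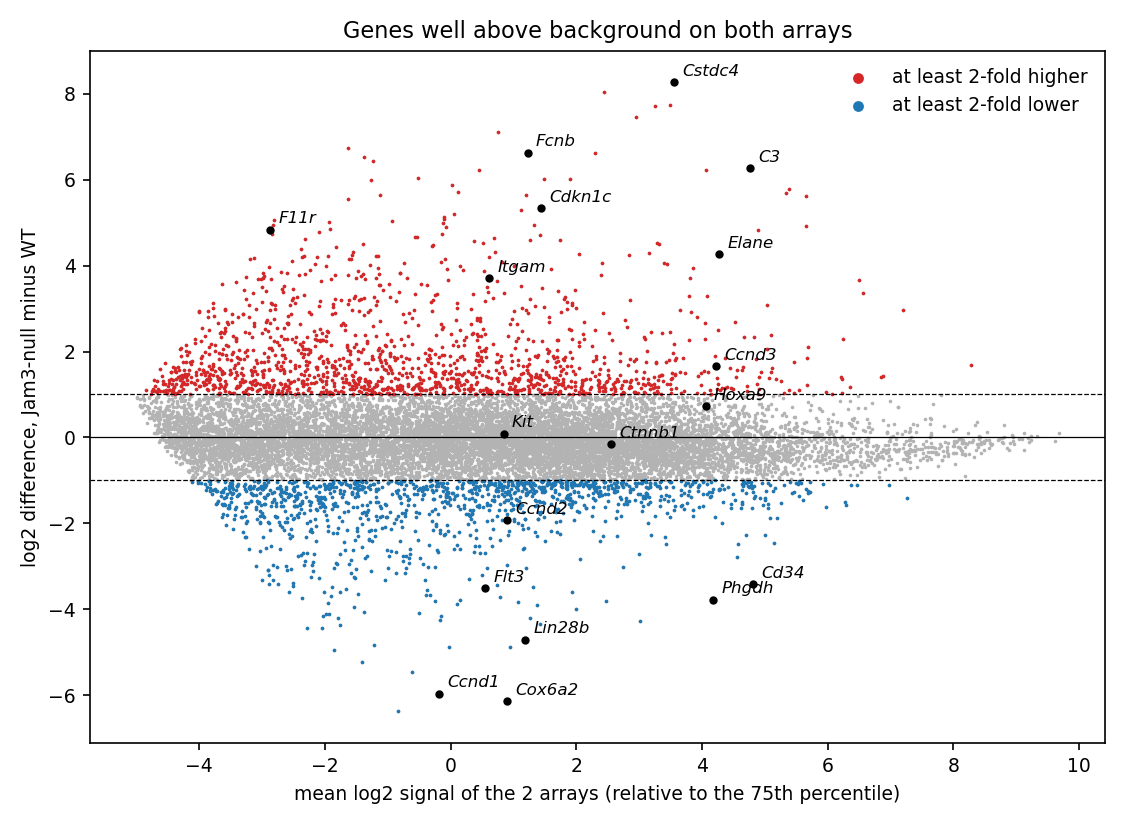
Log2 difference, Jam3-null minus WT, against the mean log2 signal of the 2 arrays, 1 point per gene well above background on both; the dashed lines mark 2-fold. Red points are the 1473 genes at least 2-fold higher and blue points the 1234 at least 2-fold lower; Cstdc4 at 8.27 and Cox6a2 at -6.15 lie near the ends of the range.

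Among the 12 brighter named genes with the largest positive differences, 6 belong to the stefin family of cysteine protease inhibitors, which sit together on chromosome 16. Their log2 differences were 8.27 for Cstdc4, 7.73 for Stfa2l1, 7.71 for Stfa2, 7.47 for Stfa3, 7.10 for Csta2 [6.47] and 5.77 for Stfa1. These genes are near-identical copies, so the signal of any one of them is uncertain. The others were Fcnb (6.63), Mogat2, an acyltransferase of triglyceride synthesis (6.62), the complement component C3 (6.27), the chitinase-like genes Chil1 (6.22 [5.60]) and Chil4 (6.22), and Scnn1a, a subunit of the epithelial sodium channel (6.01). C3 had a processed signal of 158475 on the Jam3-null array and 2200 on the WT array.

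The 12 brighter named genes with the largest negative differences began with Cox6a2, a subunit of cytochrome c oxidase (-6.15), the endothelin receptor Ednra (-4.88) and Lin28b, a regulator of let-7 microRNAs (-4.71). They went on with the zinc finger gene Zfp975 (-4.26), the major histocompatibility gene H2-Q5 (-3.90), Oaf (-3.84), Phgdh, the first enzyme of serine synthesis (-3.78), and the adhesion receptor Adgrg1 (-3.71). The last 4 were the mast cell protease Cpa3 (-3.60), Flt3 (-3.51), the chromatin organiser Satb1 (-3.48) and Tespa1 (-3.44). H2-Q5 belongs to a family of near-identical genes, and its signal is uncertain for that reason.

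Among genes seen on 1 array only, the largest bounds on the Jam3-null side were Rasgef1a at least 108-fold, Ifnlr1 at least 94.9-fold, Pik3c2g at least 89.0-fold and Dock1 at least 85.9-fold higher. On the WT side, Nrgn was at least 70.9-fold, Armcx2 at least 67.1-fold, Hnf4a at least 67.1-fold and Afm at least 34.4-fold lower on the Jam3-null array. Each bound sets the bright signal against the lowest signal well above background on the dim array. After normexp correction, with its offset, the bounds were smaller: 26.1-fold for Rasgef1a, 20.8-fold for Ifnlr1, 18.4-fold for Pik3c2g and 16.2-fold for Dock1. On the WT side they were 22.5-fold for Nrgn, 23.2-fold for Armcx2, 20.3-fold for Hnf4a and 12.3-fold for Afm.

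Of the 28 gene lists fixed before the data were examined, 11 had a median above the central 95% of 10000 random lists matched on mean signal and 3 had one below it. These percentiles describe the 2 arrays and are not a test of genotype. The remaining 14 lists lay inside it.

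**Figure D2:**
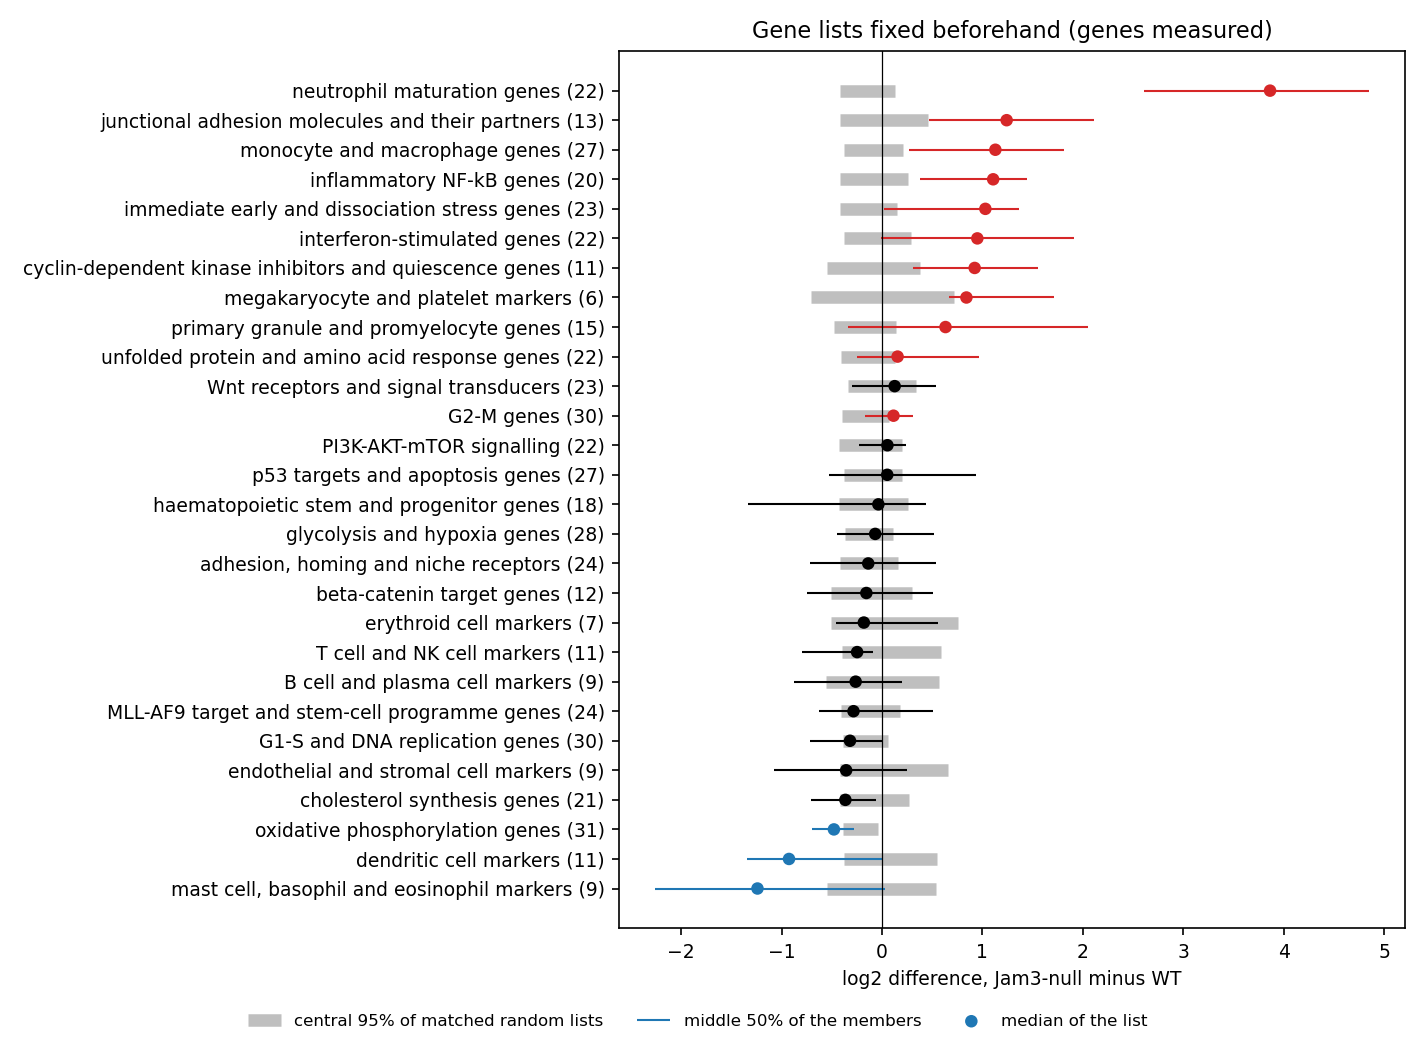
Median log2 difference, Jam3-null minus WT, of each gene list (points), the middle 50% of its members (thin lines) and the central 95% of 10000 matched random lists (grey bars), with the number of genes measured on both arrays in parentheses; red medians lie above the random range, blue below and black inside. The neutrophil maturation list has the highest median, 3.86, and the mast cell, basophil and eosinophil list the lowest, -1.24.

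Myeloid maturation genes were higher as groups. The neutrophil maturation list had a median of 3.86 and lay above all random lists, percentile 100, with Fcnb at 6.63, Itgb2l at 5.64 and Fpr2, a formyl peptide receptor, at 5.09 [4.40]. The members with the brightest signals, S100a8 and S100a9, named after their values were seen, were higher by 2.96 and 1.70. Of 15 primary granule and promyelocyte genes, 6 were at least 2-fold higher and 2 at least 2-fold lower (median 0.63, percentile 100). The neutrophil elastase gene Elane was at 4.27, Ms4a3 at 3.09 and the G-CSF receptor gene Csf3r at 2.49. Other members, named after their values were seen, were not higher by much or were lower. The brightest, Mpo and Ctsg, were at 0.11 and -0.10, and the 2 lower genes were Cst7 (-1.87) and Calr (-1.08). This list's median was 0.11 and inside the random range (percentile 96.7) when only the brighter 7180 genes were kept. Of 27 monocyte and macrophage genes, 15 were at least 2-fold higher and 1 at least 2-fold lower (median 1.13, percentile 100), with Tlr4 at 3.83 [2.19], Cybb at 3.28 and Cd14 at 3.01. The lower gene, named after its value was seen, was Irf8 (-1.34). Itgam, which encodes the Mac-1 chain used in the sort, was at 3.71.

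Inflammatory and stress genes were higher too. Of 20 NF-kB genes 11 were at least 2-fold higher and 0 lower by that much (median 1.11, percentile 100), including the chemokine genes Ccl2 (4.79 [3.28]) and Ccl5 (2.91) and the regulator Bcl3 (3.93). Immediate early and dissociation stress genes had a median of 1.03 (percentile 100), with 12 of 23 at least 2-fold higher, among them Atf3 (2.19), Klf6 (2.18) and Btg2 (1.87). Interferon-stimulated genes had a median of 0.95 (percentile 100), with 11 of 22 at least 2-fold higher and 3 at least 2-fold lower. Oas2 was at 4.43 [3.08] and Ddx58 at 4.03 [2.68], but Gbp3 was at -2.83. With the brighter genes alone, 8 of the interferon genes were left, their median was 0.22 and the percentile 87.8. The unfolded protein and amino acid response list had a median of 0.16 (percentile 98.3), and its members went both ways: the stress gene Nupr1 was at 2.43 [1.72], and the serine synthesis genes Phgdh and Psat1 were at -3.78 and -2.31. It lay inside the random range after normexp background correction (median 0.11, percentile 97.1) and with the brighter genes alone (median 0.017, percentile 90.3).

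Cell cycle genes did not move as 1 group. Of the D cyclins, Ccnd1 was at -5.97 [-5.04] and Ccnd2 at -1.93, the latter with all 3 of its probes lower, whereas Ccnd3 was at 1.67. The 30 genes of G1-S and DNA replication had a median of -0.32 (percentile 9.68), with 5 at least 2-fold lower and 2 at least 2-fold higher, and E2f2 at 2.42. The 30 G2-M genes had a median of 0.11 (percentile 98.7), where the matched random lists had a median of -0.17, and 0 of them differed by 2-fold. Mki67, a marker of dividing cells, was at 0.64, Cdc25b at 0.56 and Mad2l1 at -0.77. Of 11 cyclin-dependent kinase inhibitor and quiescence genes, 5 were at least 2-fold higher and 0 at least 2-fold lower (median 0.92, percentile 99.98). Cdkn1c was at 5.35, Btg2 at 1.87, Cdkn2d at 1.79 and Cdkn1a, which encodes p21, at 0.92. The 27 p53 target and apoptosis genes had a median of 0.05 (percentile 83.7), with the death receptor gene Fas at 3.22 [2.37], Perp at -4.94 [-3.50] and the survival gene Bcl2 at -2.97.

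**Figure D3:**
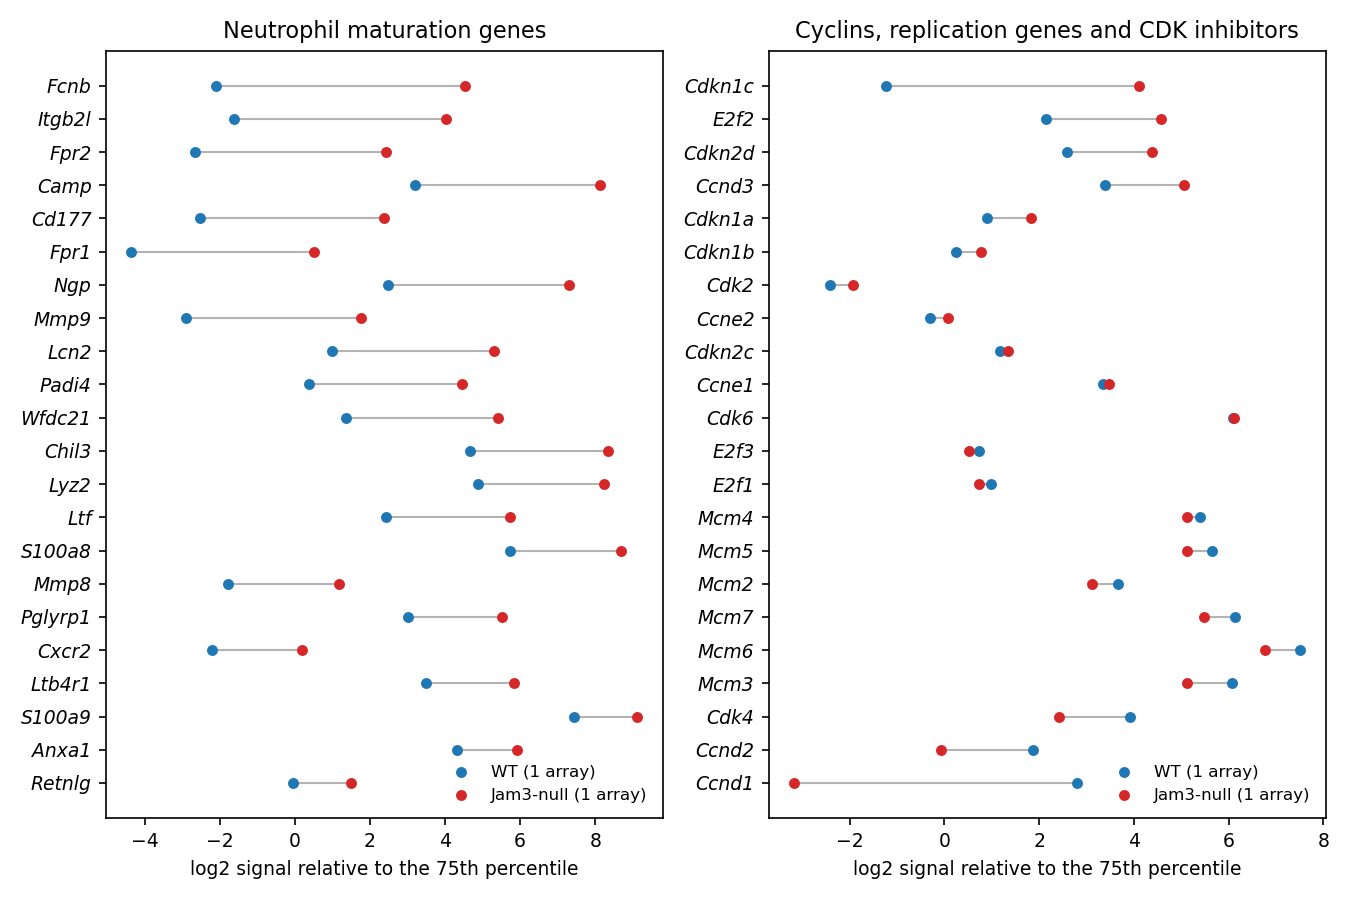
Log2 signal relative to each array's 75th percentile on the WT array (blue) and the Jam3-null array (red), 1 array each, for the neutrophil maturation genes (left) and for cyclins, cyclin-dependent kinases, their inhibitors, E2F and MCM genes (right). Every neutrophil maturation gene shown is higher on the Jam3-null array, from 1.56 for Retnlg to 6.63 for Fcnb, and the right panel runs from -5.97 for Ccnd1 to 5.35 for Cdkn1c.

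The medians of the Wnt and AKT signalling lists lay inside the random range, while single members went both ways. The Wnt receptors Lrp5 and Lrp6 were at 0.20 and 0.32, Ctnnb1, which encodes beta-catenin, at -0.15 with 2 of its probes lower and 1 higher, and Gsk3b at 0.13. The list of Wnt receptors and transducers had a median of 0.13 (percentile 81.4), with the frizzled genes Fzd9 at -4.11 [-2.81], Fzd5 at 1.56 [0.86] and Fzd4 at -1.16. The 12 measured beta-catenin target genes had a median of -0.16 (percentile 43.8), with 3 at least 2-fold higher and 3 at least 2-fold lower. They included Ccnd1 at -5.97 [-5.04], Sox4 at -3.54 [-2.45] and Plaur, 3.93-fold higher. Myc was at -0.24, and Axin2 was not well above background on either array. Of the 25 genes on this list, 9 were below background on both arrays and 3 were seen on the WT array only. Of these 3, Znrf3, named after its value was seen, had a bound of -1.59 [-0.76]. Akt1 was at -0.04, with its 2 probes differing in sign, and Akt2 at 0.12. The PI3K-AKT-mTOR list had a median of 0.05 (percentile 87.7), with Pik3r5 at 3.70 [3.01], Pik3cd at 1.28 and Foxo1 at -0.94.

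Junctional adhesion molecules and their partners were higher as a group. Of 13 measured genes, 8 were at least 2-fold higher and 1 at least 2-fold lower (median 1.24, percentile 99.98). F11r, which encodes JAM-A, was 28.7-fold higher (log2 difference 4.84 [2.98]; 7.89-fold after normexp correction), Itgam was at 3.71 and the claudin gene Cldn1 at 3.22 [1.69]. Itgam is also in the adhesion list and is a myeloid differentiation gene. Jam2 was not well above background on the Jam3-null array, and no fold is given. Other members of the group seen on 1 array only, named after their values were seen, went both ways. On the Jam3-null array only was Cxadr, with a bound of 1.85. On the WT array only were Pard6g, Esam and Cgn, with bounds of -1.83 [-0.82], -0.06 and -0.05. With genes at their bound the group's median was 1.20 (percentile 100). The 24 adhesion, homing and niche receptors had a median of -0.14 (percentile 48.1), with Vcam1 at 4.73 [4.11] and Cd34 at -3.41. Prom1 of that list, named after its value was seen, was seen on the Jam3-null array only, with a bound of 5.56 [3.60]. Another 3 of its members were seen on the WT array only.

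Stem and progenitor genes went both ways. In the MLL-AF9 target list of 24 measured genes (median -0.28, percentile 12.7), 4 were at least 2-fold lower, among them Sox4 (-3.54 [-2.45]), Flt3 (-3.51) and Bcl2 (-2.97), and 3 at least 2-fold higher. Hoxa9 and Meis1, transcription factor genes of this leukaemia, were at 0.73 and 0.81. In the haematopoietic stem and progenitor list of 18 genes (median -0.04, percentile 64.4), 5 were at least 2-fold lower, including Cd34 (-3.41), Gata2 (-3.21) and Hlf (-2.10 [-1.17]), and 2 at least 2-fold higher. The 2 higher genes, named after their values were seen, were Ly6a (1.27) and Runx1 (1.19). Another 4 members of this list were seen on the WT array only and 0 on the Jam3-null array only.

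Oxidative phosphorylation genes were lower by a small amount together, with 27 of 31 lower and 2 at least 2-fold lower (median -0.48, percentile 0.18). Ndufb5 was at -1.13, Sdha at -1.05 and Ndufv1 at -0.86. Glycolysis and hypoxia genes had a median of -0.07 (percentile 72.9), with Vegfa at 2.49, Egln3 at -2.28 and Ndrg1 at 2.02. Cholesterol synthesis genes had a median of -0.37 (percentile 4.67), with Cyp51 at -1.59 [-0.93], Mvk at -1.57 and Sqle at -1.44, and lay outside the random range after normexp background correction (median -0.39, percentile 1.75).

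Markers of other cells that a bone marrow sort could hold were measured beside these groups. Mast cell, basophil and eosinophil markers were lower on the Jam3-null array (median -1.24, percentile 0), with 6 of 9 at least 2-fold lower, including Cpa3 (-3.60), Prg2 (-2.59) and Hdc (-2.26). The size depended on the processing: their median ranged from -2.26 to -0.45 over the alternatives, below the random range in each. Dendritic cell markers were lower as well (median -0.93, percentile 0), with 5 of 11 at least 2-fold lower, including Flt3 (-3.51), Tcf4 (-2.72) and H2-Ab1 (-1.46), but this list lay inside the random range with no filter on dim probes (median -0.12, percentile 16.4). Megakaryocyte and platelet markers were higher (median 0.84, percentile 98.6) on the 6 genes measured on both arrays, with Gp9 at 2.08 and Vwf at 1.96 [1.31]. Other members of this list, named after their values were seen, went both ways: Itga2b, Pf4, F2r and Treml1 were seen on the WT array only, with bounds of -1.91 [-0.89], -1.16 [-0.43], -0.90 and -0.57, and Thbs1 and Gp6 on the Jam3-null array only, with bounds of 3.13 [1.71] and 1.06. With these genes at their bound the median was 0.68 (percentile 98.1). Erythroid markers had a median of -0.18 (percentile 19.8) over 7 genes, with Hba-a1 at 1.73 and Rhd at -1.57, and of 0.56, still inside the random range, with no filter on dim probes. The medians were -0.25 for T and NK cell markers (percentile 9.38; Il7r -3.60 [-2.34], Nkg7 1.84), -0.26 for B and plasma cell markers (percentile 18.9; Vpreb1 -4.08 [-3.47], Bank1 1.85 [1.19]) and -0.36 for endothelial and stromal markers (percentile 4.30; Pdgfrb -2.50, Nes -1.52). With no filter on dim probes the T and NK cell list lay above the random range instead (median 0.66, percentile 99.8). Of its 28 members 11 were below background on both arrays, where the signal floor lay higher on the Jam3-null array (Tjp1 -6.93 against -7.80, Fzd1 -6.97 against -7.81). How far values below background set the unfiltered medians, here and for dendritic and erythroid markers, was not tested. Members of these lists seen on 1 array only are named here after their values were seen. On the Jam3-null array only were the erythroid genes Alas2, Ahsp and Hemgn, with bounds of 3.23 [1.67], 2.39 [0.87] and 1.69 [0.65], and the T and NK cell genes Thy1, Bcl11b, Cd8b1, Cd3d and Klrb1c, with bounds of 3.35 [1.43], 2.57 [1.22], 2.55 [1.28], 2.30 [0.96] and 1.88 [0.74]. Also seen on that array only were Sdc1 of the B and plasma cell list (1.29 [0.43]) and Eng of the endothelial list (2.07 [0.77]). On the WT array only, with a bound of at least 2-fold, were the B cell genes Cd72, Vpreb2 and Spib (-2.18 [-1.10], -1.76 [-0.70] and -1.07 [-0.45]) and Prss34 of the mast cell list (-1.51 [-0.45]). With genes at their bound the medians were 0.27 for erythroid (percentile 91.0), -0.11 for T and NK cell (percentile 48.9), -0.39 for B and plasma cell (percentile 4.07) and -0.13 for endothelial and stromal markers (percentile 39.1), each inside the random range.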

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

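Scaling on the spike-in probes was chosen after the data were examined; the other alternatives were fixed before. Of the 14 lists that stood apart from random lists, 10 did so under every alternative that gave a value, and of the 14 that did not, 12 stayed inside under every such alternative. The median of the neutrophil maturation list ranged from 3.51 to 4.07. No alternative changed the sign of a named gene at least 2-fold apart, but many folds were smaller after normexp correction. After normexp correction 59 of 118 named genes moved by at least their error-model SD, all 59 towards 0, and in 34 of them the fold was more than 1.5 times smaller. The offset of 50 added to every signal was about as large as the median processed signal (49.3 and 51.6). It pulls folds of dim genes towards 0 by construction, so this direction says nothing of the background correction itself. Ccnd1 went from -5.97 to -5.04, F11r from 4.84 to 2.98, Ccl2 from 4.79 to 3.28 and the bounds of Armcx2 from -6.07 to -4.53 and of Dock1 from 6.42 to 4.02. The lists that moved over a bound were T and NK cell markers (0.66) and dendritic cell markers (-0.12) with no filter on dim probes, cholesterol synthesis (-0.39) and unfolded protein response genes (0.11) after normexp correction, and interferon-stimulated (0.22), primary granule (0.11) and unfolded protein response genes (0.017) with the stricter filter. The filters change which members are measured, and without a filter values below background enter the medians. For normexp the cause was not tested. The stricter filter left 5 lists with under 3 members and no value.

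The counts of genes at least 2-fold higher and lower became 2828 and 2920 with no filter and 521 and 567 with the stricter filter, which keep more and fewer genes by construction. They became 2647 and 2917 at 1.5-fold and 709 and 421 at 3-fold, and stayed within 1.5 times the main counts under the other alternatives. The balance of the 2 directions depended on the scaling, with 1317 higher and 1498 lower after spike-in scaling and 1761 and 985 after cyclic loess. Cyclic loess moved the median of all genes by 0.13 and the absence of a filter by 0.22. Jam3 has no fold under the main setting, so it has no value to compare. No leave-one-out and no paired analysis was possible because each group has 1 array. Signal over background limits what can be said of genes near the floor, where a fold is a bound.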

Other observations

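All groups and tests in this part were chosen after a result was seen, apart from the lists named in the report. The serine and fetal lists were written down before the members that had not prompted them were examined. As in the report, brackets hold the log2 value after normexp correction where it made a fold or bound more than 1.5 times smaller. Genes of a list for serine and one-carbon synthesis were lower on the Jam3-null array. The list holds genes that supply folate-bound carbon and genes that use it, such as Gart and Atic of purine synthesis. Of 15 measured genes 10 were at least 2-fold lower (median -1.12), and without Phgdh and Psat1, which prompted the list, the other 13 had a median of -1.08, below all 10000 matched random lists (percentile 0). Shmt2 was at -1.83, Gcsh at -1.79, Gart at -1.78 [-1.003] and Atic at -1.14, while Mthfd2 was at 0.09.

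Most genes with an H2 symbol were lower, while the interferon list stood above the random range, though not with the brighter genes alone. Of 24 genes with an H2 symbol 16 were at least 2-fold lower (median -1.41), including H2-Q4 (-1.87) and H2-T22 (-1.86), with H2-T24 at 2.46 [1.20]. The group was formed after H2-Q5 and H2-Ab1 were seen to be lower, and several members are near-identical copies, so single values are uncertain and the count is not one of separate genes. Lin28b (-4.71) prompted a list of fetal haematopoietic genes, of which the other 8 measured had a median of -0.44, inside the random range (percentile 5.46). Of genes of liver cells, 5 were seen on the WT array only, Hnf4a, Afm, Afp, Apoa2 and F2 (bounds of -6.07 [-4.34], -5.10 [-3.62], -4.27 [-2.73], -0.43 and -0.19), and 2 on the Jam3-null array only, Dlk1 and Ahsg (bounds of 4.22 [2.40] and 1.25 [0.61]); Trf was at 0.27 and Rbp4 at -1.15, and Alb, Ttr and Apoa1 were below background on both arrays. Within 10 Mb of Jam3 on chromosome 9, 21 of 115 genes (18.3%) differed by 2-fold in either direction, against 18.9% of the 14246 genes elsewhere.

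Neutrophil maturation genes were higher, while the MLL-AF9 target list and the stem and progenitor list lay inside the random range (medians -0.28 and -0.04). Against normalization or background correction as the cause of the higher values, the neutrophil list's lowest median under the 4 other normalizations was 3.51. Mature neutrophils carried into the Jam3-null sample could add to the higher values, although the c-Kit gate should remove them. The G2-M genes, at a median of 0.11, bear on non-dividing cells only. A large share of such cells would lower these genes if the leukaemia cells divided alike in both samples, which is not known. A small share stays open in either case. Carried-in maturing cells that still divide would not lower these genes, so the G2-M genes set no limit on such cells. Neither kind of carried-in cell can be told apart from maturation of the leukaemia cells. The effect of Jam3 itself stays open and untested, with 1 array per genotype.

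Y-linked genes were higher on the Jam3-null array, although both samples are labelled female: Ddx3y was at 4.16 [2.34], Eif2s3y at 4.21 [2.77] and Kdm5d at least 1.95 [0.80] in log2. Against probes that also bind the X-linked partners, the highest of the 4 partners, Kdm6a, was at -0.014. Male cells in the Jam3-null sample are a candidate explanation, since all 4 Xist probes were lower, with a median of -1.18. Xist was still bright on that array (4.51 in log2 against 5.76), Uty and Usp9y were below background, and Zfy1 and Zfy2 were at -0.17 and -0.14. If so, the 2 arrays may differ in the sex of the mice as well as in genotype, and these data cannot separate the 2.

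A group of neighbouring genes on the X chromosome was put together after low values were seen in it, so random lists are no test of it and no percentile is given. Of the 8 measured genes of the Armcx, Bex and Tceal families, 6 were at least 2-fold lower, including Armcx4 (-4.37 [-3.04]), Tceal8 (-2.62 [-1.94]) and Bex3 (-2.31). Of the 4 others in the group, Bhlhb9 was at -3.02, Gprasp1 at 0.07, Zmat1 at 0.92 and Gprasp2 at 3.83 [2.42], and the median of all 12 was -1.18. Against a lower level of X-linked genes as a whole, the other 431 X-linked genes had a median of -0.14. Against normalization or background correction, the highest median under the 4 other normalizations was -1.08. A regional difference between the leukaemias may remain, and whether it goes with Jam3 or with the animals was not tested.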
